A study of Ixodes scapularis with 21 samples.

How the data were processed

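Poly(A)-selected RNA from salivary glands of adult female blacklegged ticks (Ixodes scapularis) was sequenced in 21 bulk libraries, which the labels place in 7 groups of 3. Unfed females form the group UF, and partially fed females removed from 4 rabbits and sorted by body weight form the groups G1 to G6. Per the labels' protocols, libraries were made with a directional NEBNext Ultra II kit. The labels call the libraries of a group biological triplicates, and each library pools glands of several females: 20 in UF, 5 in G1 and G2, 3 in G3, G4 and G5, and 2 in G6. Ticks were not tied to rabbits in the sources used here, so p-values measure the spread between these pooled libraries.

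The authors deposited expected counts, TPM and FPKM per gene. Per the labels' protocols and the series design text, reads were trimmed with Cutadapt, aligned with STAR in its 2-pass mode to the assembly ASM1692078v2 and quantified with RSEM inside the RNA-seek workflow, which also ran FastQC. Tool versions, the annotation release and the strand setting were not given in the sources used here. The deposited expected counts are RSEM estimates that divide reads matching several genes among them and are not scaled to depth. The deposited TPM values are scaled by effective transcript length and depth, and the deposited FPKM values are scaled to transcript length and to the number of mapped fragments.

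The count table held 32436 identifiers, of which 29746 matched the reference table of the same assembly by symbol. Of the identifiers, 2747 were tRNA genes with 0 counts in every library. No identifier had a descriptive name and no gene had a sequence name in the reference table, so coordinates are not given and genes are identified by their symbol, annotated type and effective transcript length. For the same reason the 44 gene lists fixed beforehand, which select genes by product name and include markers of other tissues, could not be applied, and no list result, list share or list-based alternative is reported.

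Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust dispersions, TMM factors, genes kept by filterByExpr, Benjamini-Hochberg adjustment). All 21 libraries entered 1 fit with group as the only term, leaving 14 residual degrees of freedom, and 14487 genes were tested. A gene was called at an adjusted p-value under 0.05. Each fed group was compared with UF and each fed group with the next lighter one, an F test asked for any difference among the 7 groups, and a slope of log2 expression on log2 of the label weight was fitted to the 18 fed libraries over 13759 genes. The label weights were used for the slope. The comparisons, the tests, the rule for naming genes and most alternatives were fixed before the data were examined.

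The naming rule took, among called genes with at least 10 CPM in every library of the higher group and no overlap between the groups, those with the highest and lowest fitted log2 change. For the slope it took the steepest called genes with a mean of at least 10 CPM, and it also took the 10 genes with the highest mean CPM. The part of the rule that asked for a product name could not be applied, and the first 2 genes per direction are printed. Other genes named in the text were chosen after their values were seen. CPM of the tested genes were scaled with TMM factors, while CPM of co-varying sets, of untested genes and of single libraries were scaled by library totals.

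Where a gene had no count in the lower group, the fold is a lower bound against a floor of 3 counts per library. Where it had 1 to 3 counts, the fold is given with an exact 95% Poisson interval. Floors and intervals cover counting error only. Folds without 1 library keep the scaling of all libraries. Library totals ranged from 11454100 to 21432300 expected counts, so the floor lay between 0.140 and 0.262 CPM. A gene was taken to share reads with a near-identical gene when its expected count was not whole in more than 50% of the libraries with a count, which held for 3126 of the 14487 genes tested. Levels of such genes are uncertain. The number of divided reads was not measured and no partner gene was identified, so genes with few and with many divided reads are marked alike. Genes under the limit can hold divided reads too. Effective transcript length was derived from counts and FPKM.

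Shares of the transcript pool were computed from TPM and compared by exact two-sided permutation tests of 3 against 3 libraries, whose smallest possible p is 0.1. Principal components were computed from log2 CPM with a prior count of 1. Sets of genes that varied together between replicates were found by average-linkage clustering (1 - r under 0.3) of the deviations of log2(CPM + 0.5) from the group means. Genes entered with at least 10 CPM in a library and a within-group SD of at least 1.5, and sets had at least 10 genes. Neighbouring genes were adjacent in the reference table and had positions within 100000 bp. Sequence names were not given, so it was not checked that both genes lie on the same sequence. The directions of called genes were permuted 1000 times. The analyses of the pool, the sets, neighbouring genes, replicate spread and read sharing were chosen after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, and figures were drawn with matplotlib 3.10.9.

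The tests were tested on simulated counts drawn from the real means and library sizes with 200 genes changed. The other genes had equal means in all groups, and genes varied independently. Scaling and false calls where many genes differ, as against UF, were therefore not tested. For G6 against G5, edgeR recovered 34 of 100 genes changed 2-fold and 86 of 100 changed 4-fold, and called 6 of 13849 others. For G6 against UF it recovered 39 and 84 of 100, for the slope 37 and 86 of 100, and for the F test 24 and 84 of 100. For G6 against G5, DESeq2 recovered 49 and 88 of 100 and called 40 of 12870 unchanged genes. Limma-trend, run there on log CPM, recovered 36 and 86 of 100 and called 10 of 14287. The limma-trend alternatives on TPM were not simulated. The search for co-varying sets recovered 60 of 60 planted genes. In that simulation the planted genes shared the same strong pattern and the other genes varied little between libraries. Weaker sets and sets with few counts were therefore not tested.

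Library names carry sample-sheet numbers in the ranges 6 to 12 (7 libraries) and 18 to 31 (14 libraries). All UF libraries lie in the lower range, and all libraries of G3, G4 and G5 in the upper one. Alternatives were other scalings (RLE, upper quartile, library totals), DESeq2 1.42.0, limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), no filter, a filter of 5 CPM in 3 libraries, fits of the compared groups alone, the replicate number or the sample-sheet range as a block, a test against a 1.5-fold change and leaving out each library. Fits within each sample-sheet range were chosen after seeing the data, as were, for named genes, the upper quartile factors and the folds without 1 library. Counts without the co-varying sets were also chosen then. They dropped the set genes from the main results and repeated only the Benjamini-Hochberg adjustment. No library pair had identical counts.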

Results

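Salivary glands of adult female blacklegged ticks were profiled before feeding and at 6 body weights reached during partial feeding on rabbits. The label weights were 1.6 mg for unfed females (UF), 2.9 mg for G1, 7.4 mg for G2, 15.9 mg for G3, 24.6 mg for G4, 44.5 mg for G5 and 105 mg for G6, with 3 pooled libraries per group. Library totals lay between 11454100 expected counts in replicate 2 of G5 and 21432300 in replicate 2 of G1. The comparisons ask which transcripts differ between unfed and feeding glands and where along the weight gain they change.

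Unfed libraries stood apart from fed ones in the principal components of log2 CPM. The first component held 32.3% of the variance and placed the 3 UF libraries between -221 and -195.6, while the fed libraries lay between -34.7 and 74.3. The second component held 17.9%, and G1 to G4 lay between 11.4 and 86.3, against -131 to -60.5 for G5 and G6. The edgeR F test with Benjamini-Hochberg adjustment called 10238 of 14487 genes as different among the 7 groups. Of these, 3718 had their highest group mean in UF and 2143 in G6, with 494 to 1212 in each of the other groups. Over all 14487 tested genes, the 3 UF libraries lay above the other 18 in 2289 genes and those of G6 in 742, against 19 to 184 genes for each of the other groups, where chance gives 10.9 genes for a given group.

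**Figure D1:**
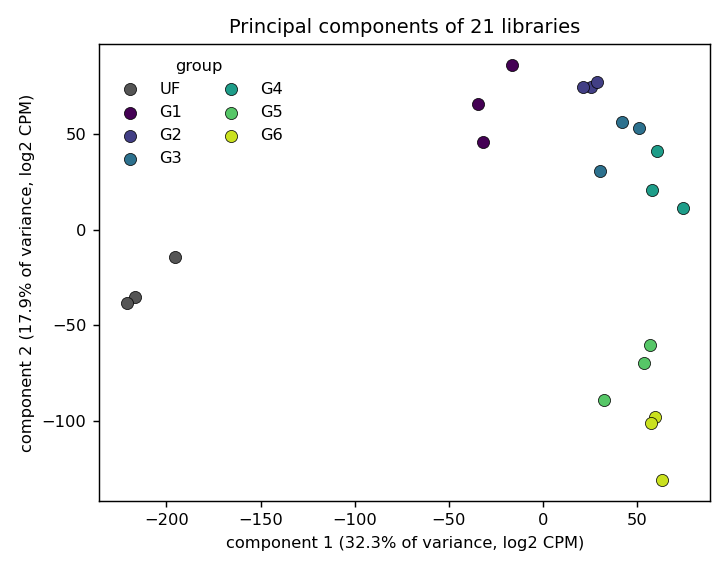
Principal components of log2 CPM for the 21 libraries, with component 1 (32.3% of the variance) on the x axis, component 2 (17.9%) on the y axis and 1 point per library coloured by group. The UF libraries lie at the left, between -221 and -195.6, and the G5 and G6 libraries lie below 0 on component 2.

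The 10 most abundant genes followed several courses from unfed to heavy females. LOC8035179 fell from 18956 ± 5311 CPM in UF (SD, n = 3) to 10008 ± 865 in G1 and 6139 ± 461 in G6, a log2 change of -1.63 (SE 0.17) between UF and G6 with an edgeR adjusted p of 3.1e-07. LOC8043622 fell from 11484 ± 3311 to 2850 ± 295 CPM over the same span (log2 change -2.01, SE 0.18, edgeR adjusted p 4.6e-08). LOC120846343 rose from 512 ± 125 CPM in UF to 11139 ± 373 in G1 (log2 change 4.44, SE 0.24, edgeR adjusted p 2.5e-10) and was at 3204 ± 826 in G6, with a falling slope over the fed groups of -0.38 per weight doubling (SE 0.05, edgeR adjusted p 3.3e-06). LOC120837176 was at 1072 ± 179 CPM in UF, 10764 ± 2144 in G3 and 3734 ± 314 in G6, and its fall from G5 to G6 was called (log2 change -0.93, SE 0.19, edgeR adjusted p 0.0038). LOC8027393 stood at 2623 ± 687 CPM in UF and 2283 ± 111 in G1 and rose over the fed groups to 7149 ± 475 in G6 (slope 0.33 per weight doubling, SE 0.02, edgeR adjusted p 4.6e-09). LOC8035570 rose from 35.4 ± 14.8 CPM in UF to 3961 ± 2138 in G1 and 13494 ± 4425 in G6 (log2 change between UF and G6 8.58, SE 0.60, edgeR adjusted p 2.5e-09). LOC8035179, LOC8035570, LOC8026527 and LOC8027393 share reads with near-identical genes, so their levels are uncertain.

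**Figure D2:**
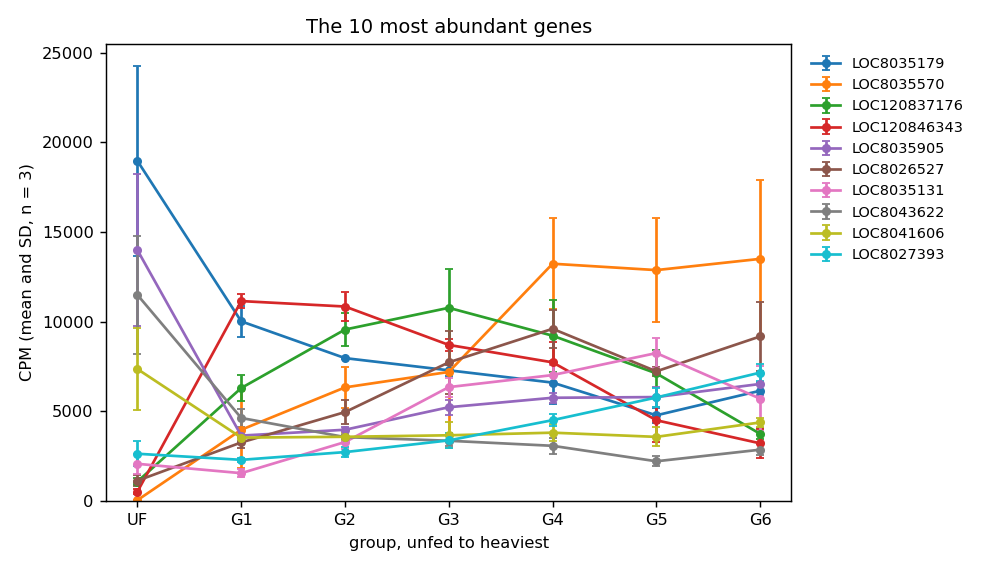
Mean CPM on the y axis for each of the 10 genes with the highest mean CPM, over the 7 groups on the x axis from unfed to heaviest, with bars for the SD of 3 libraries. LOC8035179 starts at 18956 CPM in UF and ends at 6139, while LOC8035570 starts at 35.4 and ends at 13494.

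The 100 most abundant genes of each library held a larger share of TPM in every UF library than in any fed library. They held 62.5% ± 3.98 of TPM in UF (SD, n = 3), 42.7% ± 2.71 in G1, 37.4% ± 1.19 in G4 and 40.7% ± 3.39 in G6. The exact two-sided permutation test of each fed group against UF gave p = 0.1, the smallest this design allows, so none of these differences can pass 0.05. Transcribed pseudogenes held 0.152% ± 0.0150 of TPM in UF, 0.937% ± 0.0667 in G5 and 0.726% ± 0.140 in G6 (exact p = 0.1 against UF for each fed group). Read sharing was defined from these same 21 libraries, of which 18 are fed. How far its share per group follows from that definition was not tested. Genes that share reads with a near-identical gene held 8.71% ± 0.149 of counts in UF, 13.6% ± 0.771 in G1 and 19.01% ± 1.396 in G5 (exact p = 0.1). The top 10 genes did not follow this order, with 11.6% ± 0.812 of TPM in UF, 12.2% ± 0.885 in G5 (exact p = 0.5), 11.1% ± 1.85 in G6 (exact p = 0.6), 9.16% ± 2.55 in G3 (exact p = 0.3) and 7.80% to 8.39% in G1, G2 and G4 (exact p = 0.1 each). The most abundant single gene held 1.26% to 1.48% of TPM in the UF libraries, 0.927% to 1.21% in G1, 1.05% to 1.32% in G2, 1.45% to 2.88% in G3, 1.47% to 2.27% in G4, 2.42% to 3.14% in G5 and 1.36% to 3.21% in G6. Measured by expected counts, the top 100 genes held 36.5% in UF and 26.05% to 27.3% in the fed groups.

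**Figure D3:**
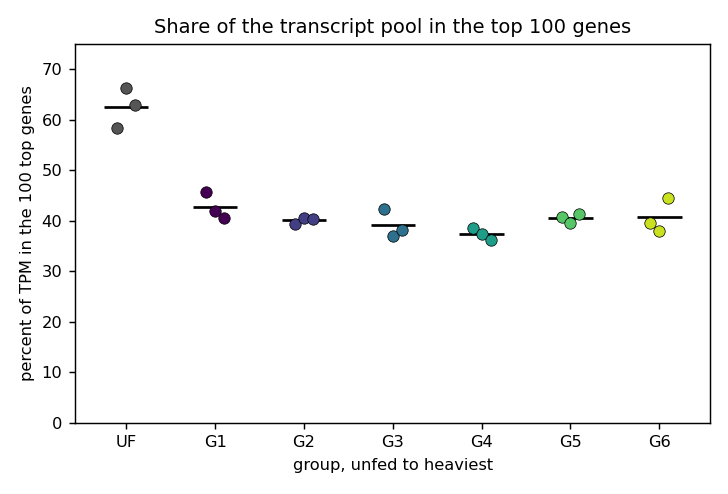
Percent of TPM held by the 100 most abundant genes of each library on the y axis, by group on the x axis, with 1 point per library and a line at the group mean. The UF libraries lie between 58.3% and 66.3%, and the fed libraries between 36.3% and 45.8%.

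Between unfed females and the lightest fed group, G1, 3556 genes were higher and 3270 lower in G1, against 3252 and 3745 with upper quartile factors and 3903 and 2666 with library totals. A fitted change of at least 32-fold was found for 537 of the higher and 174 of the lower genes. These fitted changes carry no floor and include genes without a count in UF. LOC8037210, a protein-coding gene, had no count in UF and 23.4 ± 7.27 CPM in G1, at least 143-fold higher (edgeR adjusted p 0.00057). The lncRNA LOC120846773, whose effective length is only 25 nt, stood at 86.1 ± 116 CPM in G1 and had 1 count in UF, 4854-fold higher with a counting interval of 871 to 191707 (edgeR adjusted p 0.0023). The fold of LOC120846773 was 1086 (195 to 42908) without G1 replicate 1, 2951 (529.6 to 116552) without UF replicate 1 and at least 523 without UF replicate 3. LOC121834282 fell from 27.2 ± 18.9 CPM in UF to 1 count in G1, a 1566-fold difference with an interval of 281 to 61836 (edgeR adjusted p 8.8e-06), and LOC115328381 from 26.1 ± 17.5 CPM to 1 count, a 1505-fold difference with an interval of 270 to 59463 (edgeR adjusted p 1.1e-05). For LOC121834282 the difference was 953-fold (171 to 37630) without UF replicate 3 and at least 154-fold without G1 replicate 2. For LOC115328381 it was 923-fold (166 to 36440) without UF replicate 2, 891-fold (159.99 to 35208) without G1 replicate 2 and at least 165-fold without G1 replicate 3. The genes higher in G1 had a median effective length of 1462 nt and the lower ones 2417 nt, against 1631 nt for all tested genes. All 6826 calls came from edgeR with Benjamini-Hochberg adjustment, and without UF replicate 3 the split was 2893 higher and 3177 lower. Within sample-sheet numbers 6 to 12, 4614 genes were called, 4390 of them among the 6826.

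In G2 against UF, 3844 genes were higher and 3773 lower, against 3518 and 4281 with upper quartile factors. LOC120844663 stood at 492 ± 415 CPM in G2 and 0.343 ± 0.270 in UF, 1388-fold higher (edgeR adjusted p 0.0080), or 2412-fold without UF replicate 1. LOC8038590, which shares reads with a near-identical gene, stood at 79.3 ± 102 CPM and had 3 counts in UF, 1491-fold higher with a counting interval of 510 to 7230 (edgeR adjusted p 0.00068), or 387-fold (133 to 1878) without G2 replicate 1. LOC120843768 fell from 87.6 ± 38.2 CPM in UF to 2 counts in G2, 2253-fold with an interval of 624 to 18600 (edgeR adjusted p 3.6e-08), and LOC115322464 from 156 ± 60.1 CPM to 0.0784 ± 0.0911, 2004-fold (edgeR adjusted p 1.5e-08). Their folds were 1484 (411 to 12250) for LOC120843768 without G2 replicate 3 and 5394 (968 to 213061) for LOC115322464 without G2 replicate 1. The split was 3471 higher and 3862 lower without UF replicate 2, and 3170 and 3653 without UF replicate 3. edgeR called 7617 genes in all, and 3799 within sample-sheet numbers 6 to 12, 3686 of them shared. In that range G2 has 1 library, which is assumed to vary like the other groups.

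In G3 against UF, 3935 genes were higher and 3857 lower, against 3650 and 4305 with upper quartile factors. LOC120836383 had no count in UF and 27.3 ± 13.6 CPM in G3, at least 168-fold higher (edgeR adjusted p 0.010), and LOC121836011, which shares reads in every library with a count, stood at 746 ± 921 CPM against 0.297 ± 0.196, 2630-fold higher (edgeR adjusted p 0.00017). For LOC121836011 the difference was 757-fold without G3 replicate 2, the library with its highest level, and 4009.5-fold without UF replicate 3. LOC115320984 fell from 75.9 ± 59.2 CPM in UF to no count in G3, at least 373-fold (edgeR adjusted p 9.5e-06), and LOC115322464 had 1 count left, 6924-fold lower with an interval of 1243 to 273498 (edgeR adjusted p 1.1e-08). LOC115320984 was at least 212-fold lower without UF replicate 2. LOC115322464 was at least 801-fold lower without G3 replicate 1, 4583-fold (823 to 181022) without replicate 2 and 4456-fold (799.7 to 175999) without replicate 3. edgeR called 7792 genes in all, with 3527 higher and 3994 lower without UF replicate 2, and 3206 and 3816 without UF replicate 3. No G3 library shares a sample-sheet range with UF, and with the range as a term LOC120836383 lost its call (edgeR adjusted p 0.30). Its fitted log2 change, which is no bound because UF had no count, went from 11.78 (SE 3.44) to 8.34 (SE 6.15).

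In G4 against UF, 4139 genes were higher and 4091 lower, against 3858 and 4557 with upper quartile factors. LOC115314811 had no count in UF and 60.9 ± 35.4 CPM in G4, at least 374-fold higher (edgeR adjusted p 0.0021), and LOC115319378 rose from 1 count to 157 ± 118 CPM, 8873-fold with an interval of 1593 to 350477 (edgeR adjusted p 2.9e-06). The rise of LOC115319378 was 5908-fold (1060.4 to 233365) without G4 replicate 3, 5395-fold (968 to 213078) without UF replicate 1 and at least 1065-fold without UF replicate 2. LOC8039316, annotated as a miscellaneous RNA with an effective length of 29 nt, fell from 421 ± 122 CPM in UF to no count in G4, at least 2082-fold (edgeR adjusted p 5.8e-09). LOC115328673 fell from 235 ± 83.3 CPM to no count, at least 1164-fold (edgeR adjusted p 1.0e-05). In G4, 12 genes with at least 10 CPM in every UF library had no count, and 5 genes with at least 10 CPM in every G4 library had none in UF. Without UF replicate 2 the calls were 3701 higher and 4229 lower, and without UF replicate 3 they were 3464 and 4077. edgeR called 8230 genes in all, and no G4 library shares a sample-sheet range with UF.

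In G5 against UF, 4247 genes were higher and 3759 lower, against 3978 and 4074 with upper quartile factors. LOC8038104 had no count in UF and 84.5 ± 8.34 CPM in G5, at least 519-fold higher (edgeR adjusted p 3.8e-07), and LOC120845285 rose from no count to 88.6 ± 70.4 CPM, at least 544-fold (edgeR adjusted p 0.00013), or at least 326-fold without G5 replicate 1. LOC120846677, which shares reads, fell from 85.7 ± 44.5 CPM to no count, at least 377-fold (edgeR adjusted p 0.0010), and LOC8025582 from 136 ± 92.4 CPM to 1 count, 5424-fold with an interval of 973 to 214221 (edgeR adjusted p 3.9e-08). The fall of LOC8025582 was at least 570.5-fold without G5 replicate 1 and 3557-fold (638 to 140505) without replicate 3. Calls were 3686 higher and 3911 lower without UF replicate 2, and 3425 and 3784 without UF replicate 3. edgeR called 8006 genes in all, and no G5 library shares a sample-sheet range with UF.

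In G6 against UF, 4333 genes were higher and 3976 lower, against 3881 and 4496 with upper quartile factors and 4082 and 4111 with library totals. A fitted change of at least 32-fold, again without a floor, was found for 901 of the higher and 380 of the lower genes. LOC8037210 rose from no count to 560 ± 651 CPM, at least 3436-fold (edgeR adjusted p 2.1e-05), and LOC120847016 from no count to 358 ± 224 CPM, at least 2198-fold (edgeR adjusted p 3.2e-05). Without G6 replicate 3, LOC8037210 was at least 1197-fold higher. LOC120846677 had no count in G6, at least 410-fold lower (edgeR adjusted p 0.00095), and LOC8039316 had 2 counts, 9086-fold lower with an interval of 2515 to 75026 (edgeR adjusted p 6.8e-09). LOC8039316 was at least 2084-fold lower without G6 replicate 1 and 5818-fold (1611 to 48042) without G6 replicate 3. In G6, 19 genes with at least 10 CPM in every library had no count in UF. Without UF replicates 2 and 3 in turn, 3946 genes were higher and 4078 lower, and 3613 and 3908. edgeR called 8309 genes in all, and 4485 within sample-sheet numbers 6 to 12, 4298 of them shared. The lone G6 library of that range is assumed to vary like the other groups.

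**Figure D4:**
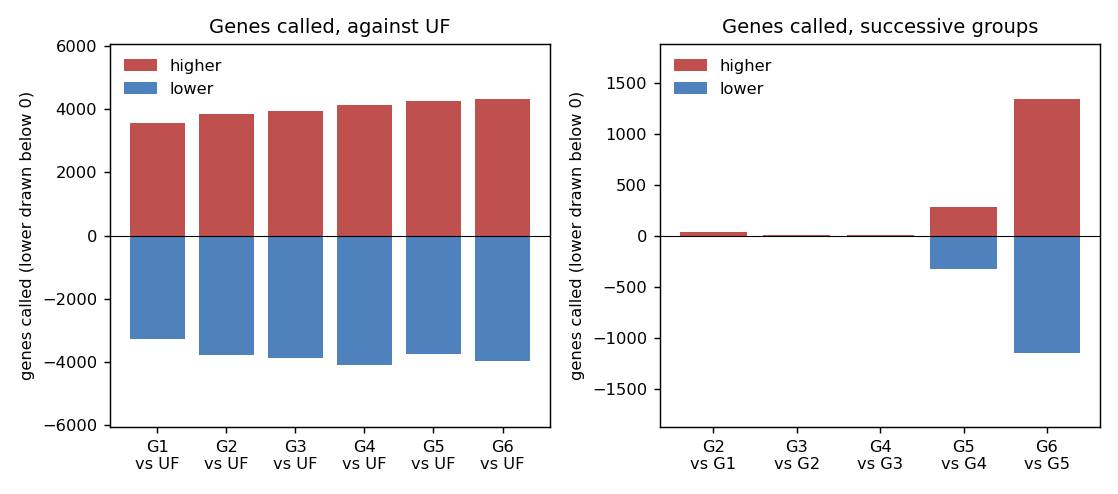
Number of genes called higher (above 0) and lower (below 0) by edgeR on the y axis, for each fed group against UF in the left panel and for successive fed groups in the right panel, which has its own scale. Against UF, between 6826 and 8309 genes were called, and between successive groups 44, 9, 10, 614 and 2497.

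Between G1 and G2, 34 genes were higher and 10 lower in G2, against 51 and 33 with upper quartile factors and 49 and 31 with library totals. LOC115318386 rose from 28.8 ± 19.5 to 293 ± 84.9 CPM (log2 change 3.35, SE 0.48, edgeR adjusted p 0.0083), and LOC8039789 from 302 ± 208 to 1959 ± 180 CPM (log2 change 2.70, SE 0.54, edgeR adjusted p 0.049). LOC8041159 fell from 494 ± 225 to 4.84 ± 3.94 CPM (log2 change -6.67, SE 0.80, edgeR adjusted p 0.0020, or -7.49 without G2 replicate 3), and LOC121836714 from 69.6 ± 12.9 to 35.4 ± 2.66 CPM (log2 change -0.98, SE 0.19, edgeR adjusted p 0.038). At an unadjusted p under 0.05, edgeR gave 1893 genes. Within sample-sheet numbers 6 to 12, where G2 has 1 library, 9 genes were called, and within 18 to 31, where G1 has 1, 1 gene was called. The lone library is assumed to vary like the other groups, and 1 gene of each range was among the 44. The count fell to 18, 25 and 4 without G1 replicates 1, 2 and 3 and to 7, 24 and 22 without G2 replicates 1, 2 and 3. LOC8039789 lost its call without any of these 6 libraries (log2 change 2.22 to 3.11, edgeR adjusted p 0.065 to 0.15), and LOC121836714 without each but G1 replicate 2 (-1.02 to -0.88, edgeR adjusted p 0.10 to 0.17). LOC115318386 lost it without G1 replicate 3 (log2 change 3.45, SE 0.59, edgeR adjusted p 0.053). With the sample-sheet range as a term LOC8039789 had a log2 change of 2.73 (SE 0.57, edgeR adjusted p 0.084) and LOC121836714 of -0.85 (SE 0.17, edgeR adjusted p 0.073), and neither was called.

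Between G2 and G3, 8 genes were higher and 1 lower in G3, against 9 and 9 with library totals and 7 and 0 with upper quartile factors. LOC8036952 rose from 38.3 ± 3.62 to 106 ± 20.6 CPM (log2 change 1.47, SE 0.25, edgeR adjusted p 0.048), and LOC8034699 from 60.7 ± 16.95 to 165 ± 14.3 CPM (log2 change 1.44, SE 0.26, edgeR adjusted p 0.048). LOC8028532 fell from 250.1 ± 23.9 to 144 ± 16.001 CPM (log2 change -0.80, SE 0.14, edgeR adjusted p 0.048), after a fall from 482 ± 80.6 CPM in G1. At an unadjusted p under 0.05, edgeR gave 1296 genes. Without G3 replicate 3 the count was 2, and without any other library of G2 or G3 it was 0 by edgeR. Over these 6 settings LOC8036952 had log2 changes of 1.33 to 1.61, LOC8034699 of 1.22 to 1.57 and LOC8028532 of -0.89 to -0.72, and none was called (edgeR adjusted p 0.059 to 0.28). With the sample-sheet range as a term the changes were 1.45 (SE 0.27), 1.58 (SE 0.25) and -0.73 (SE 0.14), and all 3 calls were lost (edgeR adjusted p 0.057 to 0.070). LOC8036952 and LOC8028532 also lost their calls with library totals (log2 changes 1.41 and -0.84, SE 0.31 and 0.17, edgeR adjusted p 0.097 and 0.079) and with upper quartile factors (1.48 and -0.78, SE 0.27 and 0.14, edgeR adjusted p 0.052). With limma-trend at a pseudocount of 1 LOC8028532 did so too (log2 change -0.82, limma adjusted p 0.11). Within sample-sheet numbers 18 to 31, 2 genes were called, 1 of them among the 9, and with only G2 and G3 fitted 3 were, none of them among the 9. DESeq2 called 187 on all libraries.

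Between G3 and G4, 10 genes were higher in G4 and none lower by edgeR. LOC8037392 rose from 2.80 ± 1.59 to 67.2 ± 32.6 CPM (log2 change 4.59, SE 0.58, edgeR adjusted p 0.0041), and LOC8023820 from 1.76 ± 0.642 to 18.9 ± 12.8 CPM (log2 change 3.42, SE 0.45, edgeR adjusted p 0.0041, or 2.71 without G4 replicate 3). At an unadjusted p under 0.05, edgeR gave 1270 genes in both directions, DESeq2 called 102 higher and 70 lower, and limma-trend 21 and 7 at a pseudocount of 1. Without G3 replicates 2 and 3 in turn edgeR called 0 genes, with LOC8037392 at log2 changes of 4.73 and 4.19 and LOC8023820 at 3.27 and 3.28 (edgeR adjusted p 0.064 to 0.082), and without G4 replicates 1, 2 and 3 it called 3, 21 and 5. Within sample-sheet numbers 18 to 31, where all these libraries lie, 17 genes were called when those of the other range were left out of the fit, 6 of them among the 10. With only G3 and G4 fitted, 1 gene was called, which was lower in G4 and not among the 10.

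Between G4 and G5, 283 genes were higher and 331 lower in G5. LOC120839568, with an effective length of only 50 nt, rose from 0.329 ± 0.161 to 1208 ± 246 CPM (edgeR log2 change 11.79, SE 2.24, adjusted p 0.012), though 1 library of G2, replicate 2, also held 433 CPM. LOC115321984 rose from 1 count to 33.4 ± 24.5 CPM, 1493-fold with an interval of 268 to 58980 (edgeR adjusted p 0.014). The rise of LOC115321984 was 886-fold (159 to 35014) without G5 replicate 3, 959-fold (172 to 37893) without G4 replicate 1 and at least 171-fold without G4 replicate 2. LOC120839539, which shares reads, fell from 36.8 ± 5.70 to 0.245 ± 0.291 CPM (edgeR log2 change -7.17, SE 1.67, adjusted p 0.029), and LOC115315635 from 67.7 ± 10.7 to 0.989 ± 0.889 CPM (log2 change -6.06, SE 0.83, edgeR adjusted p 0.0021). LOC120839539 stood at -8.77 without G5 replicate 3 and LOC115315635 at -7.12 without G5 replicate 1. The genes higher in G5 had a median effective length of 1497 nt and the lower ones 3019 nt. Limma-trend at a pseudocount of 1 called 329 higher and 660 lower, and DESeq2 830 and 748. edgeR called 614 genes in all and 714 within sample-sheet numbers 18 to 31 (482 shared), but 170, 131 and 402 without G4 replicates 1, 2 and 3, and 188, 276 and 289 without G5 replicates 1, 2 and 3. Higher genes were then the majority without G5 replicates 1 (110 of 188), 2 (153 of 276) and 3 (162 of 289). The call of LOC120839568 was lost without G4 replicates 1 and 2 (log2 changes 12.04 and 11.45, edgeR adjusted p 0.056 and 0.071). Those of LOC115321984 and LOC120839539 were lost without each G4 library (edgeR adjusted p 0.052 to 0.081), and that of LOC120839539 also without each G5 library (edgeR adjusted p 0.059 to 0.11).

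Between G5 and G6, 1344 genes were higher and 1153 lower in G6. LOC120845284 rose from 0.325 ± 0.230 to 244 ± 134 CPM (log2 change 9.52, SE 1.92, edgeR adjusted p 0.0051, or 10.26 without G5 replicate 3), and LOC121835798 from 0.340 ± 0.238 to 196 ± 87.5 CPM (log2 change 9.18, SE 1.00, edgeR adjusted p 6.3e-05). LOC115324160 fell from 37.9 ± 16.5 CPM to no count, at least 181-fold (edgeR adjusted p 0.037), and LOC115326142, which shares reads in every library with a count, from 1739 ± 1462 to 0.837 ± 0.4004 CPM (log2 change -10.99, SE 1.42, edgeR adjusted p 0.00034, or -10.29 without G5 replicate 3). LOC120839568 returned from 1208 ± 246 to 0.737 ± 0.0882 CPM (log2 change -10.66, SE 2.11, edgeR adjusted p 0.0035), and with the sample-sheet range as a term its log2 change was -12.54 (SE 1.82). The genes higher in G6 had a median effective length of 3515 nt and the lower ones 1401 nt. With library totals as the only scaling, edgeR called 956 higher and 1549 lower, and with upper quartile factors 1202 and 1448. It called 2497 genes in all, 1508 within sample-sheet numbers 18 to 31 (1337 shared), 1286 without G5 replicate 3 and 1407 without G6 replicate 3. Without G5 replicate 2, 833 were higher and 859 lower. LOC115324160 lost its call without any of the 6 libraries (edgeR adjusted p 0.055 to 0.11) and with the sample-sheet range as a term (edgeR adjusted p 0.083). Its fitted log2 change, no bound since G6 had no count, was -12.25 (SE 3.59) and became -11.60 (SE 4.00) with that term.

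Over the 18 fed libraries, 2978 genes rose and 2966 fell with the log2 of body weight. LOC115325436, which shares reads, rose from 0.0723 ± 0.125 CPM in G1 to 362 ± 345 in G6 (slope 4.22 per weight doubling, SE 0.38, edgeR adjusted p 1.3e-07, or 5.08 without G1 replicate 2 and 3.29 without G6 replicate 3), and LOC120849674, which also shares reads, from 0 to 217 ± 287 CPM (slope 4.14, SE 0.55, edgeR adjusted p 9.4e-06). LOC121835684 fell from 380 ± 628 to 0.0738 ± 0.0753 CPM (slope -4.23, SE 0.45, edgeR adjusted p 8.5e-07), with 1198 CPM in G1 replicate 3 and 3.31 CPM in replicate 2, and its slope was -2.05 without G1 replicate 3. LOC120846677 fell from 50.1 ± 11.9 CPM to 0 (slope -3.50, SE 0.38, edgeR adjusted p 9.7e-07). edgeR called 5944 of 13759 genes in all and 4776 within sample-sheet numbers 18 to 31. With library totals as the only scaling 2404 rose and 3608 fell, and by limma-trend at a pseudocount of 1 2118 rose and 3861 fell. Of the rising genes 402, and of the falling genes 125, had a fitted slope of at least 2-fold per weight doubling. For LOC115325436 and LOC121835684 the fitted slope is steeper than the means of G1 and G6 alone would give. Slopes of genes with levels near 0 in some groups are fitted values rather than measured changes per doubling.

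A set of 111 genes, named set 1 here, varied together between replicates of the same group. It held 0.00602% of counts in G1 replicate 1, 0.925% in replicate 2 and 0.312% in replicate 3, and in G6 1.65% in replicate 2 against 0.0154% and 0.0132% in the others. A second set of 57 genes held 0.0465% to 0.0972% of counts in UF, 0.111% in G1 replicate 1, and 0.0762% and 0.0164% in G6 replicates 1 and 3. In the other fed libraries it held 0.319% to 8.45%, with the highest level in G3 replicate 1. At a stricter limit on 1 - r than 0.3, 99 of the 111 genes of set 1 and 37 of the 57 genes of the second set stayed together. At a looser limit 111 and 57 did, but this is no test. Genes joined at 1 limit stay joined at any looser limit of the same clustering. The 266 genes of all 6 such sets were also dropped from the edgeR results and only the Benjamini-Hochberg adjustment was repeated. This left 6790 called genes in G1 against UF and 2504 in G6 against G5. The model was not refitted, so how the sets affect the scaling and the other genes was not tested.

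**Figure D5:**
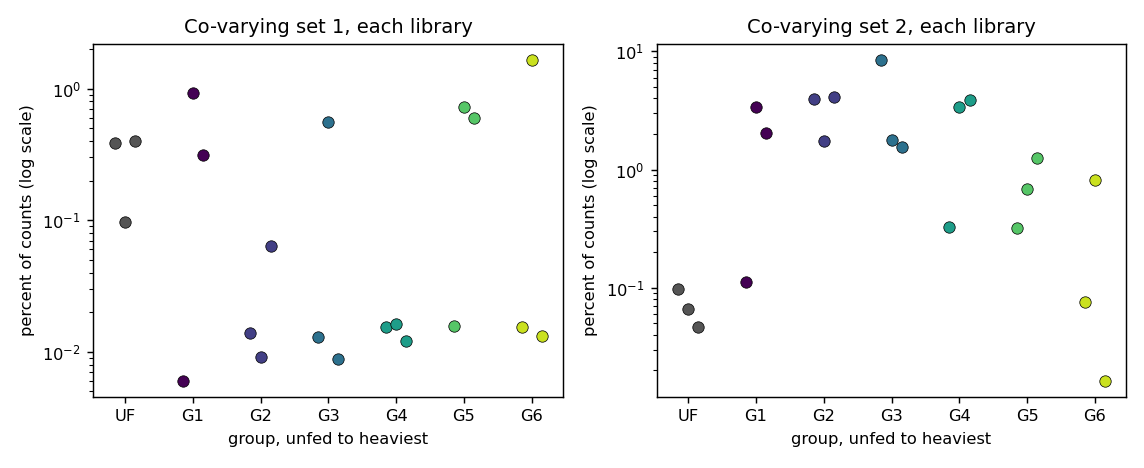
Percent of counts held by 2 sets of co-varying genes on a log y axis, by group on the x axis, with 1 point per library, for set 1 (111 genes, left) and set 2 (57 genes, right). Set 1 spans 0.0132% to 1.65% within G6, and set 2 lies at 0.0164% in 1 library of G6 and at 8.45% in 1 library of G3.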

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

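The test for signal outside the compared genes was chosen only after the data were seen. Among genes left out of the comparisons by the filter on low counts, 38 reached at least 10 CPM in a fed library and stood above every UF library, and they are listed because signal appeared in data that no comparison used. The highest value was 711 CPM for LOC115318302 in G1 replicate 3, where the other G1 libraries held 0.194 and 0.280 CPM and the UF libraries 0.0499 to 0.370 CPM. It reached 117 CPM in G5 replicate 3. LOC120846592 stood at 581 CPM in G5 replicate 3, 47.4 CPM in replicate 1 and 0.524 CPM in replicate 2, with 0 in every UF library. Of the untested genes, 18 reached 10 CPM in an UF library, 17 in replicate 1, 1 in replicate 2 and 0 in replicate 3, so that 1 was left without UF replicate 1. The 38 genes came from 18 fed libraries with a condition on UF. The UF count came from 3 libraries without a matching condition, so the counts are not alike. The filter keeps genes with enough counts in 3 libraries, so an untested gene can be high only in fewer than 3. Of the 38 genes, 5 belonged to 1 co-varying set of 18 genes, of which 0 stayed in a set at a stricter limit on 1 - r. These genes were chosen for naming after their values were seen.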

How the results depend on the processing

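Several settings below were chosen after the data were seen. They are the fits within sample-sheet ranges, the counts without the co-varying sets and the upper quartile factors for named genes. Alternatives for the pool shares and for genes named afterwards were also chosen then. The cause of each change was not tested unless fewer libraries or genes enter by construction. Of 282 alternative values of the 13 counts of called genes, 216 lay within 1.5 times the main count. Of 811 alternative values for 56 changes of named genes, 740 were called in the same direction, 71 were not called and 0 reversed, and 14 changes lost at least 1 call.

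For G2 against G1 (44 genes), the count was 84 with upper quartile factors, 80 with library totals, 462 with DESeq2, 128 and 84 with limma-trend at pseudocounts of 1 and 0.1, 29 without a filter, 102 with at least 5 CPM in 3 libraries, 7 with only these groups (3 shared with the 44), 27 with the sample-sheet block, 3 against a 1.5-fold change, and 9 and 1 within sample-sheet numbers 6 to 12 and 18 to 31, where 1 group has a lone library that is assumed to vary like the other groups. For G3 against G2 (9 genes), it was 18 with library totals (5 shared with the 9), 187 with DESeq2 (9 shared), 20 and 14 with limma-trend (4 shared by each), 5 without a filter, 15 with the stricter filter, 3 with only these groups (0 shared), 0 with the sample-sheet block, 0 against a 1.5-fold change and 2 within numbers 18 to 31. The counts of 0 are edgeR's, and without these settings edgeR gave 1296 genes at an unadjusted p under 0.05. For G4 against G3 (10 genes), it was 172 with DESeq2, 28 and 24 with limma-trend, 1 with only these groups (lower, and 0 shared with the 10), 4 against a 1.5-fold change and 17 within numbers 18 to 31. For G5 against G4 (614 genes), it was 1578 with DESeq2, 989 and 925 with limma-trend, 213 with only these groups (153 shared) and 79 against a 1.5-fold change. For G6 against G5 (2497 genes), it was 678 with only these groups (619 shared), 461 against a 1.5-fold change and 1508 within numbers 18 to 31. G2 and G6 against UF gave 3799 and 4485 within numbers 6 to 12, and the slope gave 276 against a 1.5-fold change.

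Leaving out 1 library gave 4 to 25 genes for G2 against G1, 0 to 2 for G3 against G2, 0 to 21 for G4 against G3, 131 to 402 for G5 against G4 and 1286 to 2269 for G6 against G5, and stayed within 1.5 times for the other counts.

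The labels do not tie equal replicate numbers to shared material. Deviations of same-numbered libraries had a mean correlation of 0.0195 against -0.00974 for other numbers, 16 of 63 pairs were above 0.1, and 10 of 21 libraries were closest to their own number. With the replicate block the counts were 26 for G2 against G1 and 0 for G3 against G2 by edgeR, and within 1.5 times for the rest (7 for G4 against G3, 470 for G5 against G4 and 2242 for G6 against G5). The term for the sample-sheet range called 0 genes by edgeR, with 1249 of 14487 at an unadjusted p under 0.05, and no other tool was run on it. Beside the group term it is estimated only from G1, G2 and G6, which have libraries in both ranges. It says nothing direct about UF or G3 to G5, and the lack of calls does not exclude an effect of the range.

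Upper quartile factors shifted the median log2 change against UF by -0.11 to -0.18, and library totals by 0.13 for G1 against UF and -0.14 for G6 against G5, so splits into higher and lower are relative to the scaling. Against UF, lower genes were the majority with upper quartile factors in all 6 comparisons, with library totals in G6, and with limma-trend at a pseudocount of 1 in G5 (3821 higher, 3904 lower) and G6 (3799 and 4170). They were so too with limma-trend at 0.1 in G6, DESeq2 in G2, the stricter filter in G1 to G4, only the compared groups in G4 and G6, without UF replicate 2 in G2 to G6 and without UF replicate 3 in all 6, so the split depends on single UF libraries as well as on the scaling. The share of calls that were higher was 53.8% for G6 against G5, against 38.2% with library totals, and 50.1% for the slope, against 40.0% with library totals and 35.4% and 35.2% with limma-trend. For G5 against G4 it was 46.1%, against 33.3% and 29.7% with limma-trend. For G2 against G1, G3 against G2 and G4 against G3 the shares of 77.3%, 88.9% and 100% rested on few genes, and with DESeq2 they were 65.2%, 56.1% and 59.3%. Alternatives for gene lists were not run because product names were not given in the tables used.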

Other observations

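The tests of this part other than the edgeR tests, with their bounds and the count of splits, were chosen only after the result was seen, and the genes named here were chosen after their values were seen. Small nuclear and small nucleolar RNAs held a larger share of TPM in every UF library than in any fed library. Small nuclear RNAs held 0.186% ± 0.0105 of TPM in UF (SD, n = 3) and 0.0264% to 0.0590% in the fed groups, and small nucleolar RNAs 0.0992% ± 0.00994 against 0.0140% to 0.0309% (exact permutation p = 0.1 for each fed group, the smallest this design allows). By expected counts small nuclear RNAs held only 0.00160% in UF and 0.000265% to 0.000378% in the fed groups. Small nucleolar RNAs held 0.00251% of counts in UF and 0.000403% to 0.000772% in the fed groups, so both TPM shares rest on few counts. Long noncoding RNAs held 1.96% ± 0.0255 of TPM in UF and 2.89% to 3.59% in the fed groups, but by expected counts 0.696% in UF against 0.674% in G1 (exact p = 0.8), 0.738% in G2 (exact p = 0.4) and 0.800% to 1.008% in G3 to G6 (exact p = 0.1 each). Of 100 top genes by TPM, UF libraries shared 99.3 on average with each other, 73.7 with G1 libraries and 42.7 with G6 libraries. Libraries of successive fed groups shared 80.3 to 82.8 from G1 to G4, 72.0 between G4 and G5 and 73.6 between G5 and G6, those of G1 and G6 shared 50.7, and libraries of 1 fed group shared 78.0 to 88.7 with each other.

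LOC115314729 rose from 10.2 ± 2.23 TPM in UF to 23930 ± 7188 in G5 and stood at 10684 ± 2068 in G6, with a called rise from G4 to G5 (edgeR log2 change 2.59, SE 0.51, adjusted p 0.012). That call was lost without G4 replicate 1 (2.52, SE 0.61, edgeR adjusted p 0.056) and without G4 replicate 2 (2.25, SE 0.53, edgeR adjusted p 0.060). LOC115328396 rose from 7.57 ± 2.90 TPM in UF to 20751 ± 9916 in G6 (edgeR slope over the fed groups 1.26 per weight doubling, SE 0.11, adjusted p 9.3e-08). Both LOC115314729 and LOC115328396 share reads with near-identical genes. The lncRNA LOC120841562, which also shares reads, rose from 106 ± 24.98 TPM in UF to 5700 ± 3398 in G1 (edgeR log2 change 5.53, SE 0.38, adjusted p 3.8e-09, or 4.93 without G1 replicate 2). In the second set of 57 co-varying genes, 36.8% of the genes shared reads. In that set 24 pairs of successive members, at most 3 rows apart in the reference table, had positions within 100000 bp. Neighbouring genes were called in the same direction in 193 of 326 pairs of G6 against G5 (59.2%, with 50.2% when directions were permuted, permutation p = 0.0010, the smallest 1000 permutations can give), 1 of 3 comparisons examined in this way. Without genes that share reads the share was 57.7% (158 of 274 pairs, permutation p = 0.0130). No gene had a sequence name, so it was not checked that the genes of a pair lie on the same sequence.

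The 111 genes of set 1 went up and down together between replicate libraries. The library with the highest level was the deepest of its group in 2 of 7 groups, which argues against library depth. Libraries of 1 group and 1 sample-sheet range differed at least 10-fold in 4 of 7 groups by level of the set, by 107-fold in G6, 62.9-fold in G3, 51.8-fold in G1 and 45.7-fold in G5, which argues against the sample-sheet range of the libraries as the whole cause. RNA from other cells in the dissected material and differences between individual females stay open, and neither was tested because marker lists were not matched to the identifiers.

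Few genes were called between successive groups from G1 to G4 and many from G4 to G6. The widest step in log2 weight, G1 to G2 (1.35), gave 1.76% as many calls as G5 to G6 (1.24) by edgeR, with 4 to 25 against 1286 to 2269 calls when 1 library was left out, 5.73% and 3.97% by limma-trend and 14.7% by DESeq2. Without adjustment the gap was narrower (1893 against 4487 genes at an edgeR p under 0.05). It was also narrower by size (427 against 1153 genes differing 2-fold, median absolute log2 difference 0.199 against 0.390). The widest step in log2 weight had the lower value in each. This argues against the size of the log2 step as the whole cause, although DESeq2 lies above the bound of 10% set for this test. In mg, however, G1 to G2 (2.9 to 7.4 mg) is smaller than G5 to G6 (44.5 to 105 mg). The size of the step in mg was not tested and stays open. The median replicate SD was 0.181 on the log2 scale in G1 and G2 against 0.259 in G5 and G6, which argues against wider spread in the early groups, and with only the compared groups fitted the share was 1.03%, which argues against the pooled estimate of spread. The number of females per library (3) and the sample-sheet range (18 to 31) are the same in G3, G4 and G5, where calls went from 10 (0 to 21 without 1 library) to 614 (131 to 402), and within that range G6 against G5, without G6 replicate 3, still gave 1508 calls, while the feeding stage itself stays open and was not tested, and G6 differs from G5 also in having 2 females per library.

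Single genes outside the sets differed at least 16-fold between replicates of a group in 196 cases over 159 genes. LOC120844664 stood at 0.497, 1056 and 0.608 CPM in the G2 libraries, and LOC120849365 at 5977, 1.84 and 2.04 CPM in the G3 libraries, and both had whole counts in every library. Counts were not whole in more than 50% of the libraries for 35.7% of the cases, above the 7.47% to 13.04% of all genes at 100 CPM, so shared reads may contribute, and they were not whole in at least 1 library for 135 cases (68.9%), but in 61 cases (31.1%) every count was whole, which argues against shared reads as the whole cause. Such genes made up 0.109% of genes at 100 CPM in UF with 20 females per library, 1.72% in G1 and 0.695% in G2 with 5, 0.879%, 1.25% and 1.72% in G3 to G5 with 3, and 2.43% in G6 with 2. The number of females is fixed within each group, so few females per library and the weight group cannot be told apart here, and G1 lies above G3 and G4 despite its larger pools. The spread of all genes at 10 CPM did not follow this order. Its median replicate SD on the log2 scale was 0.298 in UF, against 0.149 in G2 to 0.269 in G6 among the fed groups. These SDs rest on TMM factors, which were 1.172, 0.773 and 0.962 in UF replicates 1, 2 and 3. They were not computed with other scalings.

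For each of the 11 comparisons of 2 groups, only the real split of the 6 libraries, 1 of 10, gave as many called genes, and 10 splits are too few for a share under 0.05. The highest count among the other splits was 11 for G1 against UF (real 6826), 8 for G6 against UF (real 8309) and 0 for G2, G3, G4 and G5 against UF (real 7617, 7792, 8230 and 8006). It was 1 for each of the 5 successive comparisons (real 44, 9, 10, 614 and 2497). For the F test, 1 of 100 splits, the real one, gave as many as 10238 genes, with 1306 in the highest other, and for the slope 1 of 100 gave 5944, with 130 in the highest other, so chance assignment of libraries can be excluded for both.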
